A study of Prunus armeniaca and Prunus mume with 8 samples.

How the data were processed

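Fruit RNA of 2 species, Prunus mume (Japanese apricot) and Prunus armeniaca (apricot), was measured on 8 one-colour Agilent arrays of 1 slide, labelled with Cy3. The labels place 2 arrays in each of 4 cultivars: Ruantiaohongmei and Xiyeqing of P. mume, and Manao and Zhenkui of P. armeniaca. Per the labels, each array carried RNA of mixed stages, from stages 1 to 8 collected between 3 and 13 weeks after full bloom, and only extracts that passed a quality check were used. The labels do not say which stages entered which array, nor whether the 2 arrays of a cultivar came from separate trees, so p-values measure the spread between these samples, which may be technical. Each row of the slide held 1 cultivar of each species (Manao with Ruantiaohongmei, Xiyeqing with Zhenkui), so row and cultivar pair cannot be told apart, while species was balanced over rows and an additive row effect cancels within a row. The 2 cultivars of a row sat in different columns, so a column effect does not cancel within a row.

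The scanner files hold intensity values that Agilent Feature Extraction had background-subtracted and detrended, per the file headers, which give version 10.7.1.1; the submitters' processing notes name version 8.1. The authors also deposited a table of log2 values for the 8 arrays, with 1 value per probe (the normalization is not given in the sources used here). The medians of its columns lay between 6.71 and 6.81, and its columns correlated with the log2 scanner signals of the same arrays at r = 0.987 to 0.991 across probes. The authors' deposited comparison tables hold log2 differences, unadjusted p-values and a ratio (fold) for each probe. The p-values equalled those of a test with unequal variances on the deposited log2 values to within 1.5e-07, and the shorter deposited lists held only probes of at least 2-fold, with p-values both under and over 0.05. They left out some such probes (1418 of 1683 were listed between species), and the rule for that is not given in the sources used here. The test and the 2-fold bound were inferred from the values, since the accompanying note names neither. The species ratio in those tables is P. mume over P. armeniaca, although the file's code order is the reverse.

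The main values were log2 of the processed signal minus the 75th percentile of each array over non-control probes. Control spots and spots carrying outlier marks were left out, and the spots of a probe were averaged on the log2 scale. Of 10384 probes, 9125 were well above background on both arrays of at least 1 cultivar and were tested with limma 3.58.1 in R 4.3.3. The species fit used all 8 arrays with cultivar as a random block (consensus correlation 0.081). Cultivar pairs were contrasts in 1 fit of the 4 cultivar means. A Benjamini-Hochberg adjusted p under 0.05 was a call. A gene whose probe was not well above background on any array of a species has only a bound there: its fold is given as at least N-fold, from the brighter group's mean against the mean, per array, of the higher of the lowest signal among probes well above background and the probe's own signal.

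Signals are given on the log2 scale relative to the 75th percentile, so a level of 0 equals that percentile, and levels of different probes are not comparable. Probe descriptions came from the authors' deposited 2-fold lists: 658 probes were described, 408 of them only as expressed sequence tags, and 244 named a protein, of which 236 were tested. Descriptions therefore exist only for probes that the authors had selected on these samples, and neither the direction of a gene list nor a gene's presence in one is independent evidence. The other probes are known only by sequence identifiers: GenBank entries starting with CB or CV, where described from apricot fruit libraries, and contigs and clusters whose origin is not given in the sources used here. Probe sequences were not used here.

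Before the data were examined, 21 gene lists were fixed as word patterns over descriptions, and tested with cameraPR (preset correlation 0.01, Benjamini-Hochberg over the lists) where at least 3 members were measured; camera with an estimated correlation was an alternative. All tested probes whose description matched a pattern were used. Named genes followed a rule fixed at the same time. Its first part was restricted to called probes that name a protein and whose 4 arrays of one species lay above all 4 of the other. Of these it kept the brightest probe of each sequence identifier and of each description, and took the 12 largest differences each way. It also took up to 2 called members of each list each way, whose arrays could overlap between species. Between cultivars of a species it took up to 5 each way, with both arrays of 1 cultivar above both of the other. The thaumatin-like protein AF362987.1, the disease resistance protein EF640680.1, beta-galactosidase EF568777.1, expansin AF367459.1, phytoene synthase AY822067.1 and the single oleosin were outside this rule and were named after their values were seen. Not all genes that met the rule are described in the text, and the result of 1 is not reported here. Orthologous sequences from several Prunus species can report 1 gene, so probe counts within a gene family are not gene counts.

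Simulated data with known answers were used to check the fits on 9121 probes, of which 200 were changed. In the real data 3339 probes were called between species, so the recovery rates need not hold there. Between species, 70% of the changes of 2-fold and 96% of those of 4-fold were recovered, with 16 false calls; with 2 arrays against 2, 9% and 85% were recovered, with 8 false calls. The number of arrays limits the precision: cultivar pairs rest on 2 arrays each.

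Alternatives covered quantile normalization, normexp background correction (on the median signals, since the files lack mean signals, with an offset of 50), the authors' values, 2 other filters, other treatments of cultivar, slide row and replicate number, limma with trend and robust options, the test behind the authors' p-values, and leaving out each array. All 35 splits of the arrays into 4 and 4 were fitted without the block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.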

Results

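Signals of 10384 probes were measured in fruit of P. mume (cultivars Ruantiaohongmei and Xiyeqing) and P. armeniaca (cultivars Manao and Zhenkui), with 2 arrays per cultivar and 4 per species. The title of the series asks which genes engaged in fruit development differ between these species. Between 7807 and 8982 probes per array were well above background, the lowest number on Ruantiaohongmei replicate 2, and the median spot was 6.35 to 8.15 times as bright as its local background. Arrays of one cultivar correlated at r = 0.969 to 0.992 across probes, cultivars of one species at 0.965 to 0.987, and arrays of different species at 0.878 to 0.927. Probes are not independent replicates. The first principal component, with 68.9% of the variance, separated the species.

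**Figure D1:**
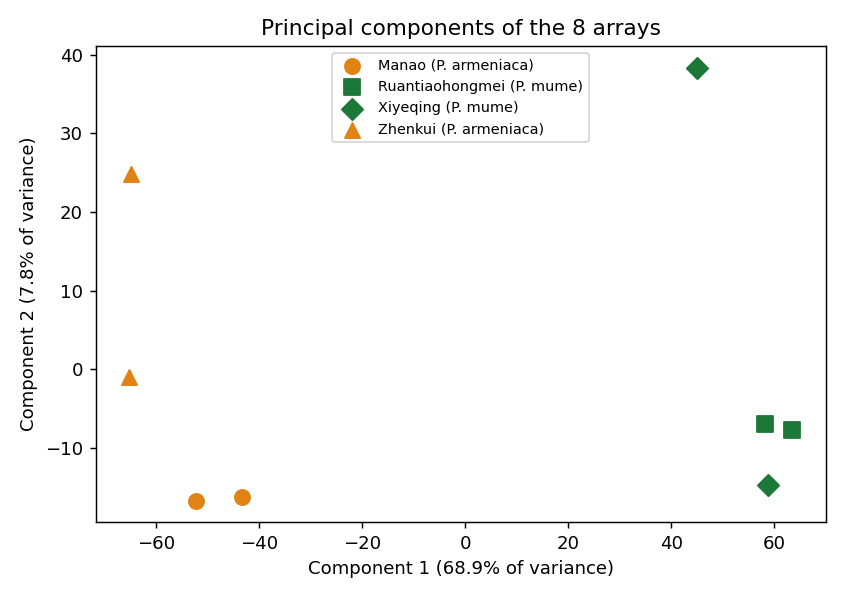
Scores of the 8 arrays on the first 2 principal components of the tested probes, 1 point per array, coloured by species and shaped by cultivar. Component 1 (68.9% of the variance) separates the 4 P. mume arrays from the 4 P. armeniaca arrays, and component 2 (7.84%) sets 1 Xiyeqing array and 1 Zhenkui array apart from the rest.

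Fruit of P. mume had far higher signals of polygalacturonase-inhibiting protein (PGIP), a cell wall protein that blocks pectin-degrading enzymes of fungi. All 9 described PGIP probes were higher in P. mume, by 5.59 to 7.22 on the log2 scale. AY903225.1 stood at 3.04 ± 1.20 (SD, n = 4) in P. mume and -4.18 ± 0.85 in P. armeniaca, a 149-fold difference (adjusted p = 7.17e-05). Across the other settings its difference went down to 5.73 on the log2 scale, and that of AY903227.1 to 4.16. Only probes in the authors' 2-fold lists were described, so PGIP probes without such a difference could not be counted. Probes for PR-10 proteins, the Bet v 1-like family of fruit allergens, rose with PGIP: a major cherry allergen (AY540509.1) was 148-fold higher (5.53 ± 1.13 against -1.68 ± 0.86, adjusted p = 4.59e-05), and PR10 (EU117120.1) was 38.7-fold higher. Fruit of P. armeniaca instead had higher signals of the dormancy-associated MADS-box genes dam2 and dam5, of the prunasin hydrolases PH B and PH C, which break down the cyanogenic glucoside prunasin, and of enoyl-CoA hydratase. The probes for dam2 (DQ863255.1) and enoyl-CoA hydratase (U93271.1) were not well above background on any P. mume array. They were at least 11.1-fold and at least 16.8-fold higher in P. armeniaca. Their adjusted p-values in the species fit (6.42e-06 and 9.22e-05) belong to the differences as scaled, not to these bounds. On each P. mume array the 2 probes had the same value, so their spread there reflects only array scaling. With normexp background correction, which has an offset, their differences were -1.64 and -2.13 on the log2 scale, under these bounds.

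Over all tested probes, limma called 3339 of 9125 between species, 1374 higher and 1965 lower in P. mume, and 1941 of the called probes differed at least 2-fold, 895 higher and 1046 lower in P. mume. With slide row as a block in place of cultivar the count was 3802, and with neither block it was 3631. The 4 arrays of one species lay wholly above those of the other for 3643 probes (39.9%), where chance gives 2.86% if all arrays are independent. Arrays of a cultivar are not independent samples of the species, and agreement between them would raise that chance share. The median difference over all probes was -0.11, and it was 0.047 with normexp background correction. In the main scaling the 9 PGIP probes lay 5.69 to 7.32 above the median probe. Their differences were smaller in another setting, down to 4.16 for AY903227.1.

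**Figure D2:**
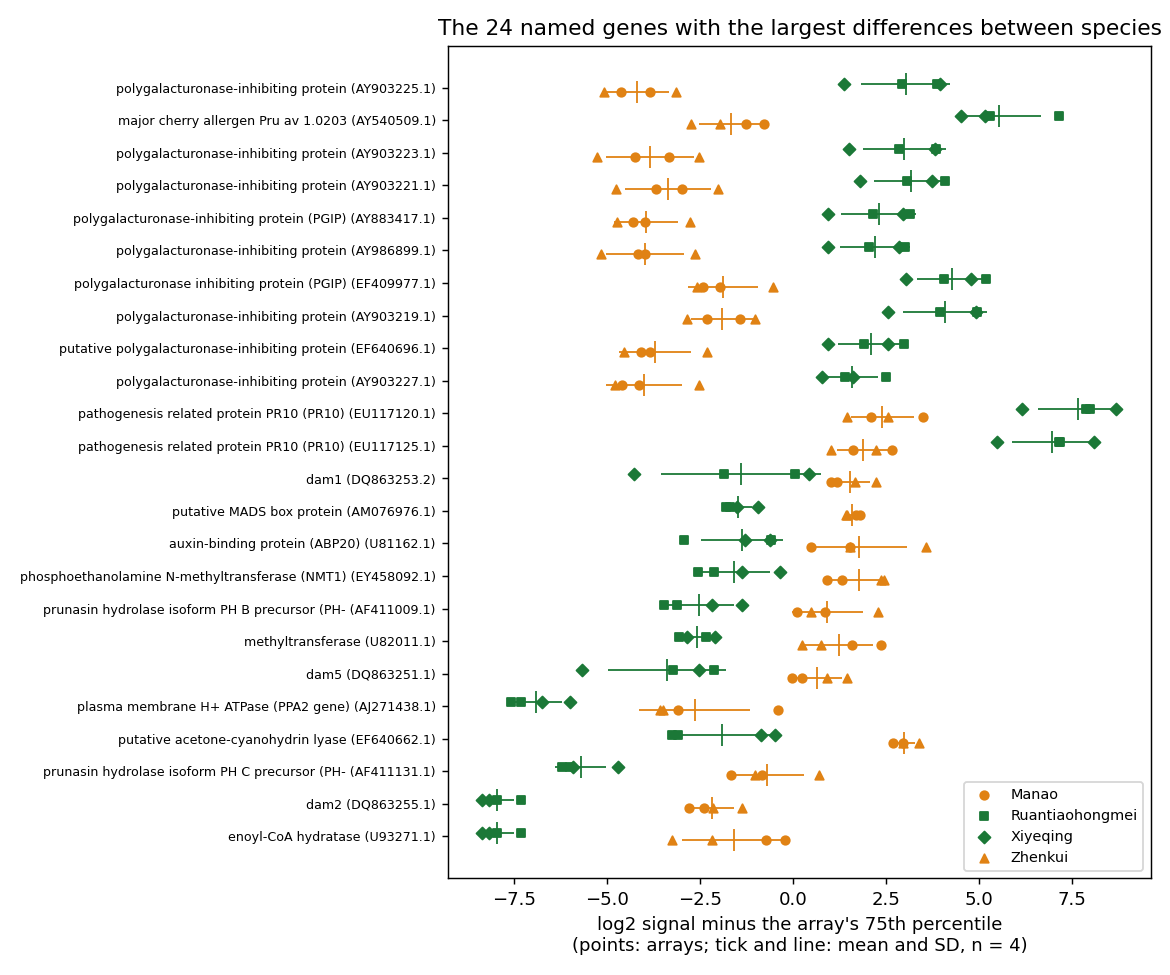
Signal of the 24 named genes with the largest differences between species, in log2 units relative to the 75th percentile of each array, 1 point per array, with the mean and SD of each species (n = 4). In P. mume the PGIP probe AY903225.1 averaged 3.04 and in P. armeniaca -4.18, and the dam2 and enoyl-CoA hydratase points of P. mume lie at the lowest level the scanner software reports.

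Defence proteins and fruit allergens were the list with the clearest shift towards P. mume. Of 24 measured probes 13 rose, 2 fell and 9 were not called (14 rose and 2 fell adjusted over the list alone), with a median of 2.36 (adjusted p = 1.6e-06 with a preset correlation and 0.294 with an estimated correlation). The rise was carried by PR-10 and allergen probes of 2.55 to 7.21, together with a thaumatin-like protein (AF362987.1, 1.48 ± 0.31 SE) and a putative disease resistance protein (EF640680.1, 1.21 ± 0.31 SE), while lipid transfer proteins LTP1 (AY093700.1, -0.87) and I (X96714.1, -0.54) fell. Within rows the list's median was 3.54 for Ruantiaohongmei over Manao and 2.09 for Xiyeqing over Zhenkui, and the list was also called against the described proteins alone (adjusted p = 0.000882). The call of X96714.1 was lost without either Ruantiaohongmei array, without Xiyeqing replicate 2 or without either Zhenkui array (adjusted p up to 0.0906). The list is drawn from probes that the authors had selected on these samples, so its direction is not independent evidence.

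Cell wall softening held 31 measured probes, of which 13 rose and 9 fell (14 and 11 adjusted over the list alone), with a median of 1.65 (adjusted p = 0.0462 with a preset correlation and 0.579 with an estimated correlation). The median was 0.72 over probes well above background on all 8 arrays. That shift rested on the PGIP probes, whose protein blocks pectin-degrading enzymes of fungi rather than loosening the wall. Among the other 22 probes 4 rose and 9 fell, with a median of -1.26 (unadjusted p = 0.11). The risers were beta-galactosidases such as EF568777.1 (3.10), whereas other beta-galactosidases (AY874412.1, 3.99-fold lower, and GAL1, AF184080.1, -1.95) fell. Of 10 expansins, which loosen cell walls, 4 fell (exp1, AF367459.1, -1.61, adjusted p = 0.00115) and 6 were not called. The call of the whole list was lost with slide row as a block in place of cultivar (adjusted p = 0.0548) and with trend and robust options (0.0941). Within rows it was lost as well (medians 1.51 and 0.21, adjusted p = 0.0937 and 0.186). It was also lost with the described proteins as background (adjusted p = 0.278), without Ruantiaohongmei replicate 1 (0.0604) or 2 (0.0902, median 0.32), without Xiyeqing replicate 2 (0.0883) and without Zhenkui replicate 2 (0.261).

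MADS-box regulators and reference genes fell in P. mume with the preset correlation. The 4 MADS-box probes of the list had a median of -1.85 (adjusted p = 0.00384 with a preset correlation and 0.294 with an estimated correlation). The list did not hold dam2 and dam5, whose descriptions did not match its pattern. Of its 4 probes 3 fell, led by a putative MADS box protein (AM076976.1) at -1.48 ± 0.38 (SD, n = 4) against 1.59 ± 0.19, 8.44-fold lower (adjusted p = 1.85e-05). All 4 fell adjusted over the list alone. All 6 reference genes fell, among them elongation factor 1 alpha (AY962821.1, -1.89), actin (FJ560908.1, -1.23) and tubulins, with a median of -1.17 (adjusted p = 0.000257 with a preset correlation and 0.294 with an estimated correlation). These genes are often taken as constant standards, and they were lower in P. mume under all 4 scalings, by 0.78 to 1.89 in the main one. Only probes in the authors' 2-fold lists were described, so MADS-box and reference gene probes without such a difference could not enter. The direction of these lists is therefore not independent evidence on either class of genes. With described proteins as background the adjusted p was 0.0568 for MADS-box and 0.0123 for reference genes. Within rows the medians were -1.96 and -1.83 for MADS-box and -1.18 and -1.18 for reference genes.

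Genes of cyanogenic glucoside breakdown moved in opposite directions. Of 6 probes 3 rose and 3 fell, and the list was not called (median 0.24, mean -0.55, adjusted p = 0.791). Prunasin hydrolase PH B (AF411009.1) fell by 3.45 and PH C (AF411131.1) by 5.00 on the log2 scale, the latter measured well above background on 1 P. mume array, and a putative acetone-cyanohydrin lyase (EF640662.1), which frees hydrogen cyanide and is not in the list, was 30.2-fold lower (-1.92 ± 1.45 against 3.00 ± 0.29, SD, n = 4). Mandelonitrile lyase MDL4 (AF053884.1) rose by 1.37. Prunasin hydrolase PH I (U50201.2) rose by 3.30 as scaled, with 3 P. mume arrays and 1 P. armeniaca array well above background. As scaled, PH I was 1.12 higher in Ruantiaohongmei than in Manao. Its rise in Xiyeqing over Zhenkui has no exact size. Both Zhenkui arrays (-8.23 and -7.01) lay under the lowest signal well above background there (-5.93 and -5.52). With normexp background correction PH C was at -2.43, PH I at 1.05 and the list's median at 0.08, and without Xiyeqing replicate 1 the median was 0.05.

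Ripening, sugar and pigment lists were not called between species, though single members differed. For ethylene, the ripening hormone, 5 of 17 probes rose and 1 fell (median 1.21, adjusted p = 0.159); the response factor ERF1b (FJ026008.1) rose by 2.23, ACC oxidase 1 (AJ890086.1), which makes ethylene, by 1.94, and the receptor ERS1 (AY061640.1) was 2.14-fold lower. The call of ERF1b was lost without Ruantiaohongmei replicate 2 or any 1 Xiyeqing or Zhenkui array (adjusted p up to 0.0797), and that of ACC oxidase 1 without any 1 Ruantiaohongmei or Zhenkui array or Xiyeqing replicate 2 (up to 0.114), and also without a filter and with trend and robust options. Without Xiyeqing replicate 1 the ethylene list was called (median 1.76, adjusted p = 0.0148), and without Ruantiaohongmei replicate 2 its median was 0.79. In the sugar and sorbitol list 3 of 6 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.97, adjusted p = 0.132), led by the hexose transporter stp2 (AF367455.1), 9.04-fold higher at 2.16 ± 0.56 against -1.01 ± 0.36, while sorbitol-6-phosphate dehydrogenase (FJ645737.1), which makes sorbitol, fell by 1.74 (0.87 with normexp background correction). In the carotenoid list 4 of 5 fell (1 rose and 4 fell adjusted over the list alone, median -1.14, adjusted p = 0.219): zeaxanthin epoxidase probes AF159948.1 and AF071888.1 fell by 2.06 and 2.03, and phytoene synthase 1 (AY822067.1) stood at 1.88 without a call (adjusted p = 0.0577). For flavonoids, phenylalanine ammonia-lyase probes (EF031063.1, -1.90) made 2 of 3 fall (median -1.90, adjusted p = 0.269), the call of PAL1 (AF036948.1) being lost without Ruantiaohongmei replicate 1 or either Xiyeqing array (up to 0.0738). Within rows the flavonoid list was called lower in Ruantiaohongmei than in Manao (median -1.51, adjusted p = 0.00648) and not called between Xiyeqing and Zhenkui (-1.93, 0.368).

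The remaining lists were likewise not called. Auxin had 1 riser and 3 fallers of 6 (1 and 5 adjusted over the list alone, median -1.99, -1.27 without Ruantiaohongmei replicate 1, adjusted p = 0.269), with ABP20 (U81162.1) 8.84-fold lower, auxin-induced protein (AY962829.1) 7.21-fold lower and auxin-repressed protein (U93273.1) 3.67-fold higher. Abscisic acid and water stress had 1 riser and 3 fallers of 5 (median -1.31, adjusted p = 0.269), including a dehydrin (DQ061115.1, -2.02). The call of the riser, an abscisic stress ripening-like protein (AF317062.1), was lost in 2 settings with all arrays, 1 of them quantile normalization. It was also lost without any 1 Ruantiaohongmei or Zhenkui array or Xiyeqing replicate 2 (adjusted p up to 0.114). The call of the faller rab21 (AF172263.1) was lost without either Xiyeqing array, Ruantiaohongmei replicate 1 or Zhenkui replicate 1 (up to 0.0915), and in 1 setting with all arrays. Organic acid metabolism had 2 fallers of 4, malate dehydrogenase (AF367442.1, -1.44) and isocitrate dehydrogenase (AF367443.1, -1.06), with a median of -0.15 (adjusted p = 0.269) that ran from -0.62 without Xiyeqing replicate 2 to 0.40 without Xiyeqing replicate 1. Heat shock proteins had 1 riser and 3 fallers of 6, with HSP60 (AF489695.1) at -1.82 (median -0.23, -0.08 without Ruantiaohongmei replicate 1, -0.36 without replicate 2 and -0.52 without Xiyeqing replicate 2, mean 0.003, adjusted p = 0.269). Aroma had 2 risers, lipoxygenase (AJ418043.2, 1.45) and alcohol dehydrogenase (EU395433.1, 1.54), and 1 faller of 5 (median 1.45, adjusted p = 0.318), with a median of -0.30 without Ruantiaohongmei replicate 2 and 0.81 without Xiyeqing replicate 2. Lignin had 1 riser of 3, cinnamoyl-CoA reductase (AF298828.1, 0.92, list median 0.91, 0.58 without Xiyeqing replicate 2, adjusted p = 0.269). Photosynthesis had 1 riser and 1 faller of 3 (1 and 2 adjusted over the list alone, median -0.91, mean -0.33, adjusted p = 0.841). Too few members were measured to test cytosolic ribosome, gibberellin and seed markers. RPS4 (AF071891.1) of the ribosome list stood at -0.94, a call lost without Ruantiaohongmei replicate 1, Xiyeqing replicate 1 or Zhenkui replicate 1. The single gibberellin probe (0.15) and the single seed marker, an oleosin (2.09 higher in P. mume, adjusted p = 0.278), were not called. No described probe matched the cell cycle or the wax lists.

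The direction of the species calls depended on the sequence a probe was designed on. Among called probes from CB and CV entries, 71.0% were higher in P. armeniaca (exact 95% interval 67.7 to 74.2%), against 71.3% of contig probes, 48.1% of actca cluster probes and 58.6% of other GenBank entries. Probes matched to a described P. armeniaca sequence gave 117 calls higher and 239 lower in P. mume, those of other Prunus species 60 and 72, and those of P. mume 3 and 0. Probe sequences were not used here, so a lower expression and a poorer match of the probe in P. mume were not separated for single genes.

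**Figure D3:**
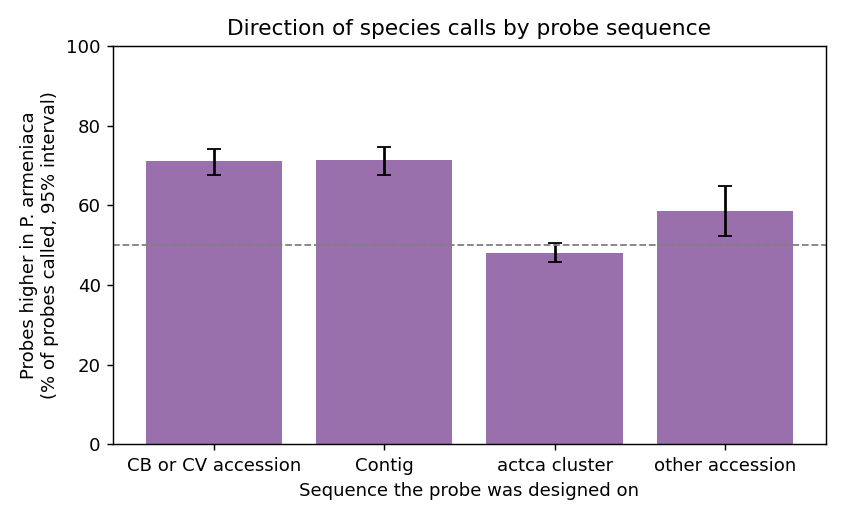
Share of called probes that were higher in P. armeniaca, in percent, by the kind of sequence the probe was designed on. Bars start at 0, lines are exact 95% intervals and the dashed line marks 50%. CB and CV entries (71.0%) and contigs (71.3%) lie above actca clusters (48.1%).

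The comparison of cultivars across species asks whether the species differences depend on the cultivars chosen. PGIP AY903225.1 was 7.64 higher in Ruantiaohongmei than in Manao and 6.79 higher in Xiyeqing than in Zhenkui, and the cherry allergen (AY540509.1) was 7.23 and 7.19 higher. Limma called 1954 probes for Ruantiaohongmei against Manao (814 higher, 1140 lower), 3183 against Zhenkui (1286 and 1897), 1459 for Xiyeqing against Manao (665 and 794) and 2577 against Zhenkui (1119 and 1458). In all 4 pairs the same way were 1103 probes, 496 higher and 607 lower in P. mume, where independent lists would share 4.32. With no effect at all, 20 simulations of unchanged groups shared 0, which does not measure what the shared arrays add to real effects. Part of the excess over independent lists may come from those arrays. The disjoint pairs, Ruantiaohongmei with Manao and Xiyeqing with Zhenkui, shared 1437 calls of one direction, where independent lists would share 282, and 5 were opposite (r = 0.847, rho = 0.785 across probes). With normexp background correction Ruantiaohongmei against Manao split into 922 higher and 786 lower. Without Manao replicate 1 it fell to 535 calls, Xiyeqing against Manao to 381 (197 higher, 184 lower) and the set of all 4 pairs to 309 (160 and 149); without Manao replicate 2 they were 639, 482 (261 and 221) and 372 (205 and 167). In Xiyeqing against Manao and in the set of all 4 pairs the larger share thus turned from lower to higher in P. mume, in the former also without Xiyeqing replicate 1 (634 and 572). Without Xiyeqing replicate 2 the set of all 4 pairs was 650 and Xiyeqing against Manao 827, and without Zhenkui replicate 1 the set was 732 and Ruantiaohongmei against Zhenkui 2011, against 1932 without Zhenkui replicate 2. Xiyeqing against Zhenkui gave 1652 calls without either Manao array, 1321 without Xiyeqing replicate 2, 1313 without Zhenkui replicate 1 and 1423 without Zhenkui replicate 2.

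Within P. mume, Ruantiaohongmei had a far lower signal of chalcone synthase (DQ856583.1), the entry enzyme of flavonoid and anthocyanin synthesis, than Xiyeqing. It stood at -3.95 in Ruantiaohongmei and 3.64 in Xiyeqing, a difference of -7.59 ± 0.47 (SE, 2 arrays each, adjusted p = 0.00063), and at 3.30 and 4.09 in the apricots Manao and Zhenkui. Inosine-5'-monophosphate dehydrogenase (AF068844.1), which makes guanine nucleotides, was 75.6-fold lower in Ruantiaohongmei than in Xiyeqing (-4.03 against 2.21, adjusted p = 5.46e-05). Across the other settings its weakest difference was -4.62 on the log2 scale, and that of chalcone synthase was -5.99. The acetone-cyanohydrin lyase (EF640662.1) was 5.62-fold lower in Ruantiaohongmei (-3.16 against -0.67, adjusted p = 0.00974). That call was lost without either Ruantiaohongmei array and without Xiyeqing replicate 1 (adjusted p up to 0.0718), and with normexp background correction the difference was -1.59. All Ruantiaohongmei and Xiyeqing arrays were well above background for these 3 probes. Each value comes from 1 probe, and probe sequences were not used here. A lower expression and a poorer match of the probe in Ruantiaohongmei were therefore not separated.

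Limma called 51 probes between the P. mume cultivars, 7 higher and 44 lower in Ruantiaohongmei, and 23 of the 44 were also lower than in both apricots. This comparison with the apricots, chosen after the data were seen, reuses the Ruantiaohongmei arrays that selected the 44, so it is not separate support. Of the 44, 23 were not well above background on any Ruantiaohongmei array, among them 14 of those lower than in both apricots. Without Ruantiaohongmei replicate 1 the calls were 18 higher and 27 lower. The count was 27 with normexp background correction and 9 over probes well above background on all 8 arrays. It was 29 without either Manao array, 28 without Ruantiaohongmei replicate 2 or either Zhenkui array, and 23 without either Xiyeqing array. The ethylene list was higher (median 1.31, adjusted p = 0.0132) and the flavonoid (median -0.28, adjusted p = 2.42e-07) and cyanogenic (median -0.69, adjusted p = 0.0135) lists lower in Ruantiaohongmei. Of the 17 ethylene and 6 cyanogenic probes 0 were called singly. The adjusted p of each list was 0.6 with an estimated correlation. The ethylene call was lost without Ruantiaohongmei replicate 2 (median -0.14, adjusted p = 0.856) and without Xiyeqing replicate 1 (0.33, 0.223). The cyanogenic call was lost without Ruantiaohongmei replicate 1 (adjusted p = 0.166) or 2 (0.0761), without Xiyeqing replicate 1 (0.503, median -0.22) and over probes well above background on all 8 arrays (0.05004). The flavonoid median was 0.05 without Ruantiaohongmei replicate 1, where the list was still called lower, and only chalcone synthase was called among the 3 flavonoid probes.

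Within P. armeniaca, the genes that set Ruantiaohongmei apart were not called between Manao and Zhenkui, with chalcone synthase (DQ856583.1) at 3.30 and 4.09 and inosine-5'-monophosphate dehydrogenase (AF068844.1) at 2.88 and 3.12. Limma gave 0 calls between them, with 1041 probes at an unadjusted p under 0.05 where chance gives 456, and the test behind the authors' p-values gave 568 unadjusted and 0 adjusted. At least 2-fold differences, without a test, were 364 higher and 85 lower in Manao, 111 and 29 with normexp background correction, and 197 and 38 on the authors' values. Of the 16 tested lists 0 were called in the main setting and 0 to 4 in the other settings. The reference genes had a median difference of -0.04 between these cultivars (adjusted p = 0.432) and the defence list of 0.09 (adjusted p = 0.657).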

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

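The test of polygalacturonase-inhibiting protein (PGIP) probes was chosen after its result was seen; the other tests were set down before the calls were counted. Among 136 groups of 4 arrays, 8 held 1 array far from the other 3, where chance gives 6.8, and 7 of the 8 follow. Ruantiaohongmei replicate 2 had a median negative control of 3.34, against 1.90 to 2.06 on the other P. mume arrays. Manao replicate 2 had the plasma membrane H+ ATPase PPA2 at -0.41 (other P. armeniaca arrays -3.56 to -3.10). Ruantiaohongmei replicate 1 had the hexose transporter stp2 at 3.00 (others 1.82 to 1.99) and the sorbitol transporter SOT1 at 0.73 (others -0.30 to -0.13). Zhenkui replicate 2 had alcohol dehydrogenase Adh-1 at 1.08 (others 2.10 to 2.16) and the dehydrin DQ061115.1 at 5.13 (others 6.02 to 6.08). Xiyeqing replicate 1 had the auxin-repressed protein at 6.67 (others 8.54 to 8.61).

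The species difference of 2 named genes changed with the cultivar pair, by a test of the difference itself. Both had been named for their large difference between Ruantiaohongmei and Xiyeqing on these same arrays. The tested difference contains that one, so it restates the result within P. mume and is not separate support. For chalcone synthase it was -7.24 between Ruantiaohongmei and Manao and -0.45 between Xiyeqing and Zhenkui, a difference of -6.79 (limma, adjusted p = 0.0141). For inosine-5'-monophosphate dehydrogenase it was -6.91 and -0.91, a difference of -6.0 (adjusted p = 0.000827). Over all probes 18 such differences were called, and 697 had an unadjusted p under 0.05, where chance gives 456. Each cultivar pair filled 1 row of the slide, and an additive row effect cancels out of a difference within a row. A column effect does not cancel. Ruantiaohongmei and Zhenkui filled columns 3 and 4 of their rows, and Manao and Xiyeqing columns 1 and 2. The tested difference sets the former 2 cultivars against the latter 2, so it cannot be told apart from a column effect.

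The 3631 probes that limma called between species without the cultivar block were not matched by other groupings of the 8 arrays. Of the 35 splits into 4 and 4, 1 gave as many, the real one, and the highest of the others gave 0. This excludes only chance in how single arrays were grouped, since every other split mixes the species. Of the splits, 3 keep cultivars whole, too few to exclude chance in the choice of cultivars. A difference in the stages pooled for each species stays open as well.

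Probes from CB and CV entries, where described from apricot fruit libraries, were more often higher in P. armeniaca. Among called probes the share exceeded that of all other probes by 15.9 percentage points (95% interval 12.2 to 19.6), which is what a poorer match of apricot probes to P. mume transcripts would give. After quantile normalization the excess was 16.3 points (12.7 to 19.9), but this test cannot decide on normalization. Neither scaling depends on a probe's origin, and the median species difference was nearly the same under both (-0.107 and -0.125). Normexp background correction, where that median was 0.047, was not tried on the excess. Probe mismatch may account for part of the excess, but contig probes, of unstated origin, had nearly the same share (71.3%), and a choice of apricot-expressed genes in those libraries stays open as well. A true species difference in expression was not tested apart from it.

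The 9 PGIP probes might have read higher in P. mume because 2 of them came from P. mume sequences. Against this, the 7 probes from other Prunus species had a median difference of 6.16, and the lowest lower 95% limit among them was 4.35. PGIP probes outside the authors' 2-fold lists carry no description and could not enter, so this covers only the described probes. A sequence change private to P. armeniaca stays open, as does a species difference in expression, stage or infection.

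A test of whether dim Zhenkui arrays explain an excess of calls higher in Manao could not be run, since limma called 0 probes in that direction (1041 had an unadjusted p under 0.05 in either direction).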

How the results depend on the processing

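Chosen after the data were seen were the tests of at least 2-fold without a test, slide row for the lists, described proteins as background, and all counts of lists within a species. So was the comparison with both apricots of the probes called lower in Ruantiaohongmei than in Xiyeqing. Each of 64 named values was tested in 14 or 15 other settings (59 of them over probes above background on all 8 arrays, 61 without the cultivar block, 0 with slide row, fixed cultivar, the authors' values or the test behind their p-values). Of the 64, 52 were called wherever tested, 12 lost their call in at least 1 setting, and 0 reversed, though normexp made the differences of the faintest smaller (dam2 -1.64, enoyl-CoA hydratase -2.13). The species count lay between 2351 (cultivars averaged, 2 against 2) and 4178 (without Manao replicate 2), except as given for 2-fold and for subsets of probes. Signal over background limits the faintest probes, and 2 arrays per cultivar limit the pairs. Arrays of the same replicate number were not taken as pairs, since their deviations correlated at -0.18 to 0.39, over 0.1 in 4 of 6 cultivar pairs, and with the replicate block the species count was 3094. Apart from settings with fewer probes or arrays, the cause was not tested.

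With normexp background correction Ruantiaohongmei against Xiyeqing had 27 calls, and over probes well above background on all 8 arrays, fewer probes, 9. The cell wall list kept its median of 1.65 but lost its call with trend and robust options (adjusted p = 0.0941) and the replicate block (0.157). The call was also lost with slide row as a block in place of cultivar (0.0548), an estimated correlation (0.579) and described proteins as background (0.278). With an estimated correlation the defence (median 2.36), MADS-box (-1.85) and reference (-1.17) lists lost theirs (each 0.294), as did MADS-box with described proteins as background (-1.85, adjusted p = 0.0568). The cyanogenic list, not called, kept its median of 0.24 while its test changed direction with an estimated correlation (adjusted p = 0.983) and over probes above background on all 8 arrays (0.815). Subsets of probes gave 356 species calls on described P. armeniaca, 3 on P. mume and 132 on other Prunus sequences. At least 2-fold without a test gave 2168 for species, 449 for Manao against Zhenkui (111 higher and 29 lower in Manao with normexp, 197 and 38 on the authors' values) and 440 for Ruantiaohongmei against Xiyeqing.

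The test behind the authors' p-values gave, unadjusted, 568 for Manao against Zhenkui, 233 for Ruantiaohongmei against Xiyeqing, 1323 for Ruantiaohongmei against Zhenkui, 1154 for Xiyeqing against Zhenkui, 1368 for Ruantiaohongmei against Manao, 1172 for Xiyeqing against Manao and 224 for all 4 cross-species pairs. After Benjamini-Hochberg each of these 7 counts was 0, while the species count was 2519; each group of a pair has its own spread from 2 arrays in this test. Lists called between Manao and Zhenkui were 2 with quantile normalization, 4 with normexp, 1 over probes above background on all 8 arrays and 2 with the replicate block. With an estimated correlation 0 lists were called between Ruantiaohongmei and Xiyeqing.

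Leaving out each array in turn, which leaves 1 cultivar with a lone array assumed to vary like the others, gave 23 to 45 calls for Ruantiaohongmei against Xiyeqing, 535 to 2087 for Ruantiaohongmei against Manao, 1932 to 3299 for Ruantiaohongmei against Zhenkui, 381 to 1596 for Xiyeqing against Manao, 1313 to 2713 for Xiyeqing against Zhenkui and 309 to 956 in all 4 pairs. Species counts ran from 2557 to 4178. Medians ran from 0.79 to 1.76 for the ethylene list, 0.32 to 2.03 for cell wall, -1.12 to -0.65 for photosynthesis, -0.30 to 1.78 for aroma, -0.62 to 0.40 for organic acids, -2.37 to -1.27 for auxin, -0.52 to -0.08 for heat shock and 0.58 to 1.19 for lignin. Lists called ran from 0 to 4 for Manao against Zhenkui and from 1 to 7 for Ruantiaohongmei against Xiyeqing.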

Other observations

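Some of the strongest contrasts between species were on probes without a gene name, singled out after their values were seen. The cluster probes actca_Cluster3645.seq.Contig1 and actca_Cluster3871.seq.Contig1 were called higher in P. mume (adjusted p = 9.82e-06 and 1.04e-05), with all 4 P. mume arrays and 1 P. armeniaca array well above background, so no size is given. In the other direction, CV052221.1 was at least 231-fold higher in P. armeniaca, with 0 P. mume arrays well above background. Its adjusted p in the species fit (2.28e-06) belongs to the difference as scaled, not to the bound. Beyond 64-fold, counting probes at background level in 1 species as scaled, 27 actca cluster probes were called higher in P. mume and 0 lower, while for CB and CV probes these counts were 0 and 6.

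In the authors' deposited table, lists of at least 2-fold held 1418 probes between species, 208 between Manao and Zhenkui and 190 between Ruantiaohongmei and Xiyeqing. Of these lists, 10.9%, 84.1% and 78.4% of probes had an authors' p-value over 0.05. The spike-in control probes had a median signal equal to the negative-control level on every array (1.90 to 3.34), so they gave no separate check of scaling.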
